A study of Mus musculus with 24 samples.

How the data were processed

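The series holds RNA-seq of an adult mouse hypothalamic neuronal cell line in 24 libraries, 3 for each of 8 groups made of 2 glucose media and 4 treatment levels. The groups and replicate numbers were read from the sample titles. NG and HG were read as the normal and high glucose of the series design, C as the control without mogroside V, and the numbers 1 to 3 as dose labels. Per the labels' protocols, RNA was extracted with the PureLink RNA Mini Kit with DNase treatment, and libraries were made from polyadenylated RNA with the VAHTS Universal V8 RNA-seq kit. The deposited files hold whole-number read counts per gene, not normalized, 1 file per library. The submitters' processing notes name FastQC 0.11.9, STAR 2.7.5c, HTSeq 1.99.2 and DESeq2 3.16 and the genome build GRCm39. The strand setting of the counting is not given in the sources used here, so a gene and an overlapping antisense gene cannot be told apart. No coordinates are printed, because the annotation used here belongs to another build than GRCm39.

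Each file lists 56941 gene IDs and 5 HTSeq summary lines, which stayed out of library sizes and tests. The lines for reads outside genes, ambiguous reads and reads aligned to several places took 14.4 to 20.6%, 3.46 to 4.15% and 16.5 to 18.9% of the reads of a library. Symbols were found for 51948 IDs, which hold 91.8% of gene counts. The ID ENSMUSG00000119584, with no symbol in that table, took 4.93 to 10.3% of the gene counts of a library.

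Of the 24 files, 2 from different groups (HG2 replicate 3 and HG3 replicate 2) were identical line by line. The design fixed beforehand had all 24 libraries in 1 fit. This was departed from after the files were compared. Both were left out, since nothing says to which dose the library belongs. Fits with all 24 files, or with that file in HG2 or in HG3, were added as alternatives. All main values therefore rest on 22 libraries, with n = 2 in HG2 and HG3.

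Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, with TMM factors, the default low-count filter over the 8 groups, group means as the design and robust quasi-likelihood F tests. P-values were adjusted by the Benjamini-Hochberg method within each of 13 comparisons, with a threshold of 0.05. The filter kept 13281 genes and removed 43660 IDs. The fit had 14 residual degrees of freedom and a common biological coefficient of variation of 0.149. CPM values are given as mean ± SD over libraries, and log2 fold changes as estimate ± standard error. Counts of called genes were recomputed with DESeq2 1.42.0. At a depth of 3396249 to 7773074 gene counts in the 22 libraries, there was a median standard error of 0.23 on the log2 scale for HGC against NGC and 0.12 for all high-glucose against all normal-glucose libraries.

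Gene lists were 42 pathways, complexes, cell type markers and signs of RNA quality, of which 41 had at least 3 tested members. They were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry, and adjusted over the lists of a comparison. Camera compares a list with all other genes, whereas fry asks whether its genes move one way on balance. Correlations of dose effects were set beside 20 simulations of unchanged groups that shared the same controls. Each gene was drawn independently, with the same mean in all groups and thus no difference between the media.

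The tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. For a comparison of 2 groups the rule takes the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between replicates. For the comparison over all dose levels the same sign at the 4 levels replaces the overlap. Where fewer than 10 genes pass, it adds the 5 lowest p-values, and it takes up to 4 members of each list with the lowest p and a fixed set of glucose, insulin, feeding and sweet taste genes. Interactions take 5 rises and 5 falls. Some genes the rule takes are not reported here. Of the genes the rule gives, those described for HGC against NGC were narrowed, after the values were seen, to genes called in every fit that left out 1 library, apart from Irs2 and the fixed set. Of the 20 largest changes in that comparison 7 held in all such fits, and 19 of 20 over all dose levels.

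Alternatives were DESeq2, RLE factors, no low-count filter, only the groups of a comparison in the fit, the replicate number as a block, each library left out in turn, fry, an estimated correlation and a minimum of 5 CPM for correlations. Added after seeing the data were the treatments of the identical file, a fit without NG3 replicate 3 and HGC replicate 2, which stood apart, and a fit with each library's trend on transcript GC content removed.

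The pipeline was tested on simulated counts of the 13281 genes with 200 changed. For HGC against NGC it recovered 19.4, 59.7 and 81.8% of genes changed 1.5-fold, 2-fold and 4-fold, with 9 false among 116 calls. For NG1 against NGC the shares were 35.8, 58.2 and 72.7%, for HG2 against HGC 14.9, 52.2 and 78.8%, and for the interaction of dose label 1 they were 7.46, 26.9 and 77.3%. Over all dose levels they were 59.7, 83.6 and 93.9%, with 7 false among 165 calls. Among 41 simulated lists, the 1 whose genes changed 1.3-fold was called at a camera adjusted p of 1.26e-12, and 0 unchanged lists were called. The simulated genes were drawn independently, so this cannot show how often camera calls unchanged lists whose genes move together. A GC trend put into 1 library fell from a correlation of 0.777 to -0.0126 after removal.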

Results

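Polyadenylated RNA of a mouse hypothalamic neuronal cell line was sequenced after culture in normal or high glucose, without or with mogroside V, the sweet triterpene glycoside of monk fruit. The 8 groups of 3 libraries were read from the sample titles as normal-glucose control (NGC), normal glucose with dose label 1, 2 or 3 (NG1, NG2, NG3), high-glucose control (HGC) and high glucose with the same dose labels (HG1, HG2, HG3). The series design lists 15, 60 and 160 µM mogroside V, but no label ties a dose number to a concentration, so only the dose labels are used here. Counts assigned to genes ranged from 3272671 to 7773074 over the 24 files, with a median of 3822823. The group means ± SD were 4546068 ± 575201 in NGC, 3837873 ± 345712 in NG1, 5097553 ± 2321069 in NG2, 4016284 ± 265926 in NG3, 3838882 ± 360061 in HGC and 3733646 ± 125003 in HG1 (n = 3 each). They were 3655654 ± 366854 in HG2 and 3756388 ± 136233 in HG3 (n = 2 each). HG2 replicate 3 and HG3 replicate 2 held identical values on all 56946 lines, with 3272671 gene counts in each. Because 1 library cannot belong to both doses, both were left out, which leaves 22 libraries.

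Between 16535 and 18935 genes had at least 1 count in a library. The fewest were in NG3 replicate 3, which also had the smallest share of reads outside annotated genes (14.4%) and the smallest mitochondrial share (5.43%) of all libraries. On the first 2 principal components of log2 CPM, with 11.1% and 9.6% of the variance, NG3 replicate 3 lay at -54.7 and -43.0, far from all other libraries. HGC replicate 2 had the lowest second coordinate of the high-glucose libraries (-24.1). The remaining normal-glucose libraries lay between -11.2 and -3.23 on the first component, and the high-glucose libraries between 9.07 and 19.3. Replicates of a group differed by more than counting noise in each of the 20 pairs of the libraries kept, with a chi-square per degree of freedom of 3.56 to 23.4. No label says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

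**Figure D1:**
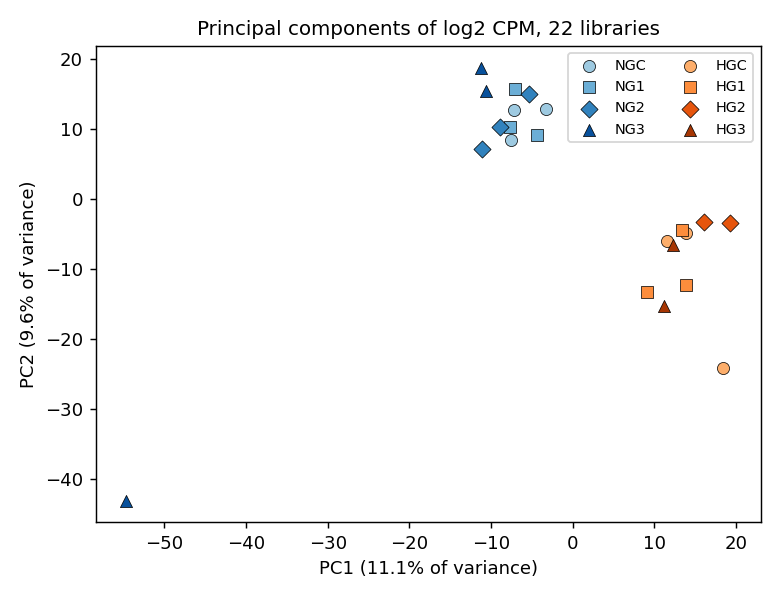
Principal components of log2 CPM over the 22 libraries, with the first component on the horizontal and the second on the vertical axis (percent of variance in brackets) and 1 point per library, blue for normal and orange for high glucose. Apart from NG3 replicate 3 at -54.7 on the first component, the normal-glucose libraries lie at or below -3.23 and the high-glucose libraries at or above 9.07.

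The first comparison asked how the untreated cells differed between high and normal glucose (HGC against NGC, n = 3 each). Cox6a2, the heart and muscle form of a cytochrome c oxidase subunit, fell by 3.91 ± 0.42 (SE) on the log2 scale, from 26.0 ± 3.82 to 1.71 ± 1.58 CPM (mean ± SD; edgeR adjusted p = 9.65e-08). Mmp3, a secreted matrix metalloproteinase, rose 2.75-fold, from 289 ± 44.6 to 792 ± 166 CPM (log2 1.46 ± 0.13, adjusted p = 2.33e-10). Mt1, which encodes a metal-binding metallothionein, rose 2.39-fold (log2 1.26 ± 0.11, adjusted p = 2.33e-10). Plin4, a coat protein of lipid droplets, rose 5.22-fold (log2 2.39 ± 0.34), and Gpnmb, a transmembrane glycoprotein of lysosomes and the cell surface, rose 3.07-fold, from 11.6 ± 1.31 to 35.6 ± 1.71 CPM. Slc7a3, a transporter of cationic amino acids, and Dusp6, a phosphatase that inactivates ERK, fell by 1.91 ± 0.37 and 1.07 ± 0.18 on the log2 scale.

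In all, 251 genes rose and 52 fell between HGC and NGC at an edgeR adjusted p under 0.05, of which 60 and 12 changed at least 2-fold. In 302 of the 303 the replicates of both groups did not overlap, a state that 17.8% of all tested genes reached and that chance gives to 10%. The calls were made on these same replicates, so this is no separate support for them. Elobl rose 4.76-fold, from 133 ± 16.2 to 632 ± 37.5 CPM. Its sequence is close to that of Elob, so its counts are uncertain. Wnt16, which encodes a secreted signalling protein, rose 3.26-fold, from 3.75 ± 0.881 to 12.2 ± 2.83 CPM. Bhlhe40, a transcriptional repressor, rose 2.16-fold, and Igfbp4, which binds insulin-like growth factors, rose 1.76-fold. The count of 303 was 163 without NGC replicate 1, 184 without NGC replicate 2 and 166 without HGC replicate 2, and 120 of the 303 genes were called in all 6 fits that left out 1 library.

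Genes of cholesterol synthesis and uptake rose together in HGC. Of 25 tested members, 15 rose, 10 did not pass, and all 25 had a positive log2 change with a median of 0.69. Adjusted over the list alone, 19 rose (camera adjusted p = 2.99e-31, and adjusted p = 3.96e-06 with an estimated correlation). Hmgcs1, the enzyme that makes HMG-CoA, rose from 135 ± 29.6 to 257 ± 24.7 CPM (log2 0.93 ± 0.13, adjusted p = 3.71e-06). The later sterol enzymes Nsdhl, Msmo1 and Cyp51 rose by 0.98 ± 0.17, 0.77 ± 0.11 and 0.70 ± 0.12 on the log2 scale. In the list of cholesterol efflux, 3 of 8 members rose, and 3 adjusted over the list alone (median 0.37, camera adjusted p = 0.000497, and adjusted p = 0.0308 with an estimated correlation). Npc2, which moves cholesterol out of lysosomes, rose 1.57-fold (log2 0.65 ± 0.10).

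Genes of lysosomes and autophagy rose in 14 of 28 tested members, and in 17 adjusted over the list alone, with a median log2 change of 0.54 (camera adjusted p = 2.51e-23, and adjusted p = 0.000149 with an estimated correlation). Hexa, a subunit of the lysosomal enzyme hexosaminidase, rose 2.16-fold (log2 1.11 ± 0.14), and Lamp2, a lysosomal membrane protein, rose 1.66-fold (log2 0.73 ± 0.10). Of 16 genes of fatty acid synthesis, 2 rose, and 9 adjusted over the list alone (median 0.29, camera adjusted p = 7.72e-07, and adjusted p = 0.00536 with an estimated correlation). Scd2, a fatty acid desaturase, rose by 0.71 ± 0.11. Of 31 genes of the extracellular matrix and TGF-beta signalling, 5 rose and 0 fell at adjusted p under 0.05 in edgeR. Adjusted over the list alone, 5 rose and 1 fell (median 0.13, camera adjusted p = 7.72e-07, and adjusted p = 0.0286 with an estimated correlation). Apart from Mmp3 these included Tgfb2 (log2 1.02 ± 0.18), Lox, which crosslinks collagen (0.90 ± 0.10), and Postn (0.81 ± 0.15). Fibroblast and pericyte markers had 7 of 9 positive log2 changes (fry adjusted p = 0.0137, but camera adjusted p = 0.102). Astrocyte and tanycyte markers had 6 of 6 negative ones (fry adjusted p = 0.0723, camera adjusted p = 0.0894). In glycolysis and lactate metabolism 1 of 20 genes rose, and 2 adjusted over the list alone (median 0.21, camera adjusted p = 0.0140, and adjusted p = 0.0414 with an estimated correlation). Ldhb, a lactate dehydrogenase subunit, rose 2.12-fold (log2 1.09 ± 0.21), while Hk2 (0.27 ± 0.16, adjusted p = 0.549) and the glucose transporter gene Slc2a1 (0.18 ± 0.18, adjusted p = 0.768) did not pass.

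Camera called 5 more lists between HGC and NGC whose call was lost with an estimated correlation. Genes of mitosis had 24 of 24 negative log2 changes with a median of -0.21, and 0 of them fell over all genes but 3 adjusted over the list alone (camera adjusted p = 3.55e-06, but adjusted p = 0.104 with an estimated correlation). At an unadjusted p under 0.05 edgeR counted 1585 of all 13281 genes in this comparison, and DESeq2 called 391. In the immediate early list 2 of 25 genes fell, and 4 adjusted over the list alone (median -0.14, camera adjusted p = 0.0137, but adjusted p = 0.441 with an estimated correlation and 0.165 without HGC replicate 2 and NG3 replicate 3). The lists of insulin, IGF and leptin signalling (2 of 25 rose; alone, 3 rose and 1 fell), of gluconeogenesis and glycogen (1 of 13, and 1 alone) and of ER chaperones (1 of 22, and 1 alone) were higher at camera adjusted p = 0.0140, 0.0390 and 0.0219. Their adjusted p was 0.0973, 0.0973 and 0.113 with an estimated correlation, and that of gluconeogenesis and glycogen was 0.130 by camera without HGC replicate 2 and NG3 replicate 3. Herpud1, a gene of ER protein degradation, rose by 0.80 ± 0.15. Irs2, an adaptor of the insulin receptor, had a log2 change of 0.93 ± 0.23 and an edgeR adjusted p of 0.0373. That p was 0.0637, 0.1098 and 0.127 without NGC replicate 1, 2 or 3, and 0.0744, 0.0966 and 0.121 without HGC replicate 1, 2 or 3. It was 0.0578 with the replicate number as a block, 0.0557 with GC trends removed and 0.133 without HGC replicate 2 and NG3 replicate 3, in a range from 2.20e-07 over all alternatives. Txnip, a gene that carbohydrate-response factors induce in many cells, had a log2 change of -0.73 ± 0.22 that did not pass in edgeR (adjusted p = 0.117), and passed without NGC replicate 1 (adjusted p = 0.0172), with DESeq2 (0.0158) and without a low-count filter (3.74e-05). Its adjusted p ranged from 3.74e-05 to 0.366 over all alternatives. Arrdc4, a relative of Txnip, stood at -0.22 ± 0.36 (adjusted p = 0.884).

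**Figure D2:**
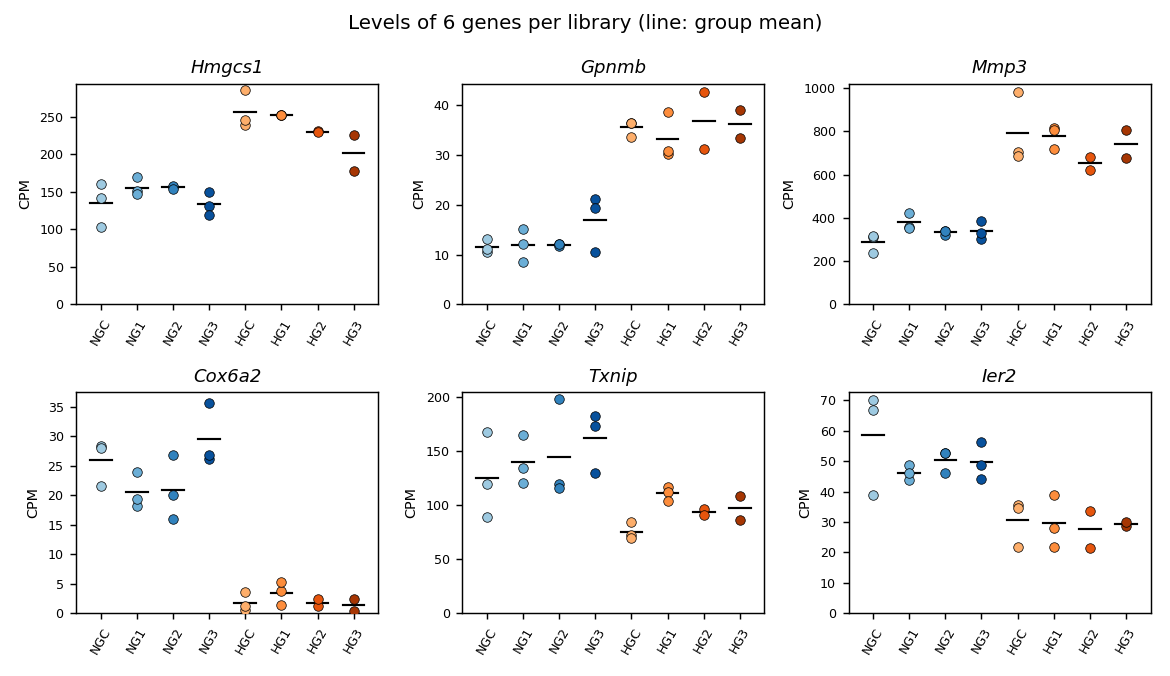
Levels of 6 genes in CPM (vertical axis, from 0) in each library, by group on the horizontal axis, with 1 point per library and a line at the group mean. Hmgcs1, Gpnmb and Mmp3 are higher and Cox6a2 is lower in the high-glucose groups, with 26.0 CPM of Cox6a2 in NGC and 1.71 CPM in HGC.

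The second comparison set all high-glucose against all normal-glucose groups, as the mean of the 4 dose levels (10 against 12 libraries). Fabp4, a fatty acid carrier protein of adipocytes and macrophages, rose 5.51-fold, from 2.35 ± 1.38 to 13.02 ± 4.73 CPM (log2 2.46 ± 0.23, edgeR adjusted p = 1.39e-10). Uap1l1, a relative of the enzyme that makes UDP-N-acetylglucosamine, rose 2.38-fold, from 78.8 ± 12.1 to 187 ± 14.5 CPM (log2 1.25 ± 0.07, adjusted p = 1.34e-16). Cox6a2 fell by 3.60 ± 0.23 on the log2 scale, Card10 by 1.18 ± 0.17, and Ccn1, a secreted matricellular protein, by 1.06 ± 0.19. Plin4, Gpnmb and Elobl, whose counts are uncertain, rose by 1.91 ± 0.18, 1.45 ± 0.12 and 2.03 ± 0.07. Hmox1, the inducible heme oxygenase, and Mt1 rose 2.26-fold and 2.04-fold, whereas Nqo1, another gene of the antioxidant list, fell by 0.72 ± 0.10 on the log2 scale.

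In all, 758 genes rose and 582 fell, 63 and 27 of them at least 2-fold. Of these 1340 genes, 1183 (88.3%) had the same sign at all 4 dose levels, against 26.6% of all tested genes. Of the 303 genes called between HGC and NGC, 256 were among the 1340 with the same direction. The 1340 were called on the mean of these 4 differences, which include HGC against NGC, so neither share is independent support. The treated libraries alone, which share no library with the controls, gave the same sign for 242 of the 251 genes that rose and 43 of the 52 that fell in HGC. Among these, 168 and 24 were also called there. The median log2 change of the 251 was 0.76 between the controls and 0.41 in the treated libraries, that of the 52 was -0.72 and -0.30, and the correlation over all genes was 0.289. These genes were picked on the controls, which inflates their changes there. The smaller changes in the treated libraries therefore do not show that treatment weakened the difference between the media. Leaving out 1 library gave between 958 and 1597 genes.

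Of the 11 lists called between HGC and NGC, 9 were called over all dose levels, which include the same control libraries. Insulin, IGF and leptin signalling (camera adjusted p = 0.500) and gluconeogenesis and glycogen (0.229) were not called. In cholesterol synthesis and uptake 22 of 25 genes rose, and 24 adjusted over the list alone (median 0.56, camera adjusted p = 1.83e-42, and adjusted p = 6.83e-07 with an estimated correlation), with Msmo1 at 0.75 ± 0.06, Hmgcs1 at 0.70 ± 0.07 and Acat2 at 0.68 ± 0.07. In lysosome and autophagy 16 of 28 rose and 1 fell, and 17 rose and 1 fell adjusted over the list alone (median 0.37, adjusted p = 2.42e-19, and 0.000331 with an estimated correlation). Ctsd, which encodes the protease cathepsin D, rose 1.43-fold and Hexa 1.64-fold. In the matrix and TGF-beta list 11 of 31 rose and 3 fell, and 14 rose and 4 fell adjusted over the list alone (median 0.19, adjusted p = 5.25e-09, and 0.0101 with an estimated correlation). Mmp3 and Lox rose by 1.15 ± 0.07 and 0.69 ± 0.05. In glycolysis and lactate 5 of 20 rose, and 5 adjusted over the list alone (median 0.14, adjusted p = 0.000412, and 0.00864 with an estimated correlation). These included Pfkl (0.55 ± 0.08), Hk2 (0.50 ± 0.09), Ldhb (0.64 ± 0.11) and Ldha (0.28 ± 0.06). In fatty acid synthesis 7 of 16 rose, and adjusted over the list alone 9 rose and 1 fell (median 0.16, adjusted p = 0.000415, and 0.0286 with an estimated correlation), with Elovl6 at 0.41 ± 0.09 and Scd2 at 0.31 ± 0.06.

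Stress and proliferation genes were also called over all dose levels. In the integrated stress response 7 of 22 genes rose, and 8 adjusted over the list alone (median 0.17, camera adjusted p = 0.00106, and 0.0101 with an estimated correlation). Atf4, its central transcription factor, rose 1.57-fold and Chac1, a glutathione-degrading target of it, 2.23-fold. Among ER chaperones 7 of 22 rose, and adjusted over the list alone 11 rose and 3 fell (median 0.17, adjusted p = 0.00106, and 0.0343 with an estimated correlation), with Hspa5 at 0.31 ± 0.05 and Calr at 0.24 ± 0.05. In mitosis 12 of 24 genes fell, and 14 adjusted over the list alone (median -0.21, adjusted p = 2.07e-08, and 0.0469 with an estimated correlation). Ccnb1, Cdk1 and Bub1b fell by 0.39 ± 0.06, 0.33 ± 0.06 and 0.40 ± 0.08. In the immediate early list 7 of 25 fell, and adjusted over the list alone 9 fell and 1 rose (median -0.28, adjusted p = 0.000412, but adjusted p = 0.264 with an estimated correlation). Egr1, Ier2 and Dusp6, genes induced within minutes of growth factor signals, fell by 0.88 ± 0.13, 0.80 ± 0.11 and 0.66 ± 0.10. Ribosome biogenesis (4 of 24 rose, and 8 alone), cholesterol efflux (3 of 8 rose, and 3 alone) and hypoxia (3 of 18 rose and 1 fell; alone, 5 rose and 1 fell) were higher at camera adjusted p = 0.00301, 0.00335 and 0.0447. DNA replication (2 of 28 fell, and 2 alone) was lower at 0.0255. Ribosome biogenesis had a median of 0.14 here but of -0.00212 between the controls (camera adjusted p = 0.629), and of -0.13, -0.28 and -0.14 in NG1, NG2 and NG3 against NGC. The adjusted p of these 4 lists was 0.122, 0.0522, 0.0957 and 0.0538 with an estimated correlation, and that of hypoxia was 0.0769 by camera without HGC replicate 2 and NG3 replicate 3.

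Of the fixed set of glucose, insulin, feeding and sweet taste genes, Txnip fell by 0.61 ± 0.12 on the log2 scale, from 143 ± 33.3 to 94.1 ± 16.3 CPM (edgeR adjusted p = 0.00187). At the levels control, dose label 1, 2 and 3 its log2 change between the media was -0.73 ± 0.22, -0.33 ± 0.22, -0.64 ± 0.25 and -0.73 ± 0.25. Irs2, of the same set, rose by 0.54 ± 0.12. Arrdc4 (0.12 ± 0.19) and Slc2a1 (0.20 ± 0.09, adjusted p = 0.175) did not pass. Npy1r, a neuropeptide Y receptor, rose from 1.67 ± 1.14 to 4.31 ± 1.63 CPM (log2 1.35 ± 0.33, adjusted p = 0.00455), and Map2, a microtubule protein of neurons, fell by 0.39 ± 0.08. Of the 11 tested neuronal markers, Map2 was the 1 that passed over all genes, and 3 rose and 3 fell adjusted over the list alone (median 0.05, camera adjusted p = 0.787). No label gives a culture or library batch, so a batch that coincides with the medium cannot be told apart from it.

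**Figure D3:**
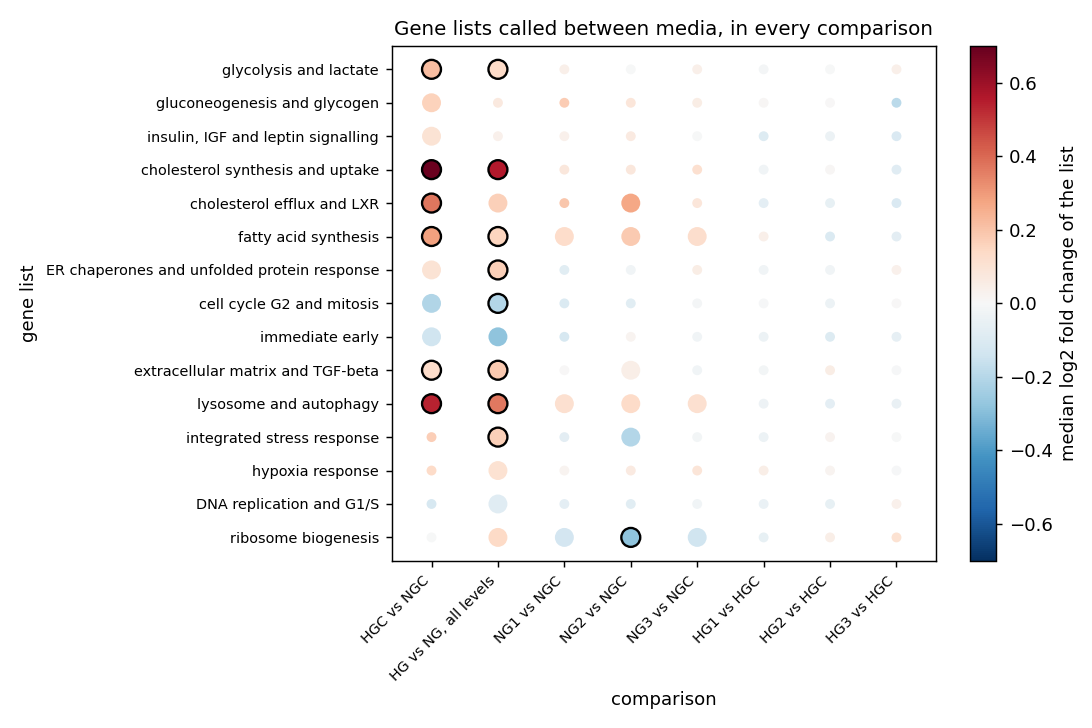
Median log2 fold change (colour) of the gene lists called between the media, with lists on the vertical and comparisons on the horizontal axis. Large points have a camera adjusted p under 0.05, small points do not, and a black ring marks a list that also passes with an estimated correlation. Cholesterol synthesis has the darkest points between media (0.69 and 0.56), and ribosome biogenesis in NG2 has the only ring among the dose comparisons (-0.28).

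The dose comparisons asked whether mogroside V changed the transcriptome in each medium. In normal glucose, NG2 differed from NGC (n = 3 each) in Tmtc1, an enzyme that adds mannose to proteins in the ER, which rose 1.95-fold, from 19.9 ± 1.91 to 39.1 ± 5.63 CPM (log2 0.96 ± 0.18, edgeR adjusted p = 0.0355). Genes of ribosome biogenesis were lower in NG2, with 22 of 24 negative log2 changes and a median of -0.28. None of the 24 passed edgeR's test over all genes that the low-count filter kept (0 in edgeR; 858 of 13281 genes had an unadjusted p under 0.05 and DESeq2 called 25), but 10 fell adjusted over the list alone (camera adjusted p = 2.30e-13, and adjusted p = 0.00443 with an estimated correlation). In the same comparison nuclear-retained RNAs, a sign of RNA quality, were lower in 5 of 6 members (median -0.25, camera adjusted p = 0.0200, but adjusted p = 0.166 with an estimated correlation; 1 fell adjusted over the list alone). The snoRNP proteins Nop56, Nop58 and Dkc1 had log2 changes of -0.57 ± 0.15, -0.55 ± 0.13 and -0.54 ± 0.13. Nop58 and Dkc1 passed in DESeq2 (adjusted p = 0.0336 and 0.0310), and all 3 passed in edgeR without a low-count filter (Nop56 0.0463, Nop58 0.00650, Dkc1 0.0197), as did Dkc1 without NG3 replicate 3 and HGC replicate 2 (0.0167). Their highest adjusted p over all alternatives was 0.9995. Abi3bp (0.73 ± 0.15) and Igfbp4 (0.54 ± 0.11), both at edgeR adjusted p = 0.107, passed in DESeq2 (0.00719 each), without a low-count filter (0.00748 each) and without NG3 replicate 3 and HGC replicate 2 (0.0114 and 0.0101), with a highest adjusted p of 0.813 over all alternatives. The adjusted p of Tmtc1 was 0.0964, 0.550 and 0.111 without NGC replicate 1, 2 or 3, and 0.0649 and 0.349 without NG2 replicate 2 or 3, so the count of 1 gene became 0 in each of these fits. DESeq2 gave no adjusted p for Tmtc1 in this comparison, so its absence from the 25 genes that DESeq2 called does not count against it.

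Camera called 8 further lists in NG2, each lost with an estimated correlation. Higher were fatty acid synthesis (camera adjusted p = 0.00190; with an estimated correlation, adjusted p = 0.0893), lysosome and autophagy (0.0104; 0.1998), cholesterol efflux (0.0218; 0.166), matrix and TGF-beta (0.0345; 0.352) and fibroblast and pericyte markers (0.0382; 0.166). Lower were cytosolic ribosomal proteins (9.86e-06; 0.482), the integrated stress response (0.0218; 0.0893) and heat shock proteins (0.0302; 0.171). Adjusted over the list alone, 1 of 16, 0 of 28, 2 of 8, 3 of 31 and 0 of 9 members rose in the higher lists. In the lower lists 0 of 68, 1 of 22 and 5 of 15 fell, and 1 heat shock gene rose. In edgeR over all genes 0 members of these lists passed.

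NG1 held 0 genes past edgeR's threshold against NGC (n = 3 each), with 648 of 13281 genes at an unadjusted p under 0.05, where chance gives 664, and 0 called by DESeq2. The lowest p-values included those of Cyp4v3, a fatty acid hydroxylase (log2 1.16 ± 0.29), and Igfbp4 (0.42 ± 0.11), both at adjusted p = 0.902. Camera gave 3 lists, lysosome and autophagy (higher, median 0.11, adjusted p = 0.000703), fatty acid synthesis (higher, median 0.13, 0.00805) and ribosome biogenesis (lower, median -0.13, 0.0186). With an estimated correlation their adjusted p was 0.239, 0.239 and 0.407, and adjusted over the list alone 0 of 28 and 1 of 16 rose and 1 of 24 fell. Camera called the same 3 lists in the same directions in NG2 and NG3. Lysosome and autophagy and fatty acid synthesis were also higher in HGC against NGC. All these comparisons share the NGC libraries, so a list that is high or low there by chance can recur with no dose effect.

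NG3 differed from NGC (n = 3 each) in 17 genes, of which 1 rose and 16 fell. Gm1673 rose 2.04-fold, from 23.8 ± 2.73 to 48.4 ± 5.36 CPM (log2 1.03 ± 0.21, edgeR adjusted p = 0.0445). Mphosph8, a reader of methylated histone H3, fell by 0.82 ± 0.15 (adjusted p = 0.0343), and the translation initiation factors Eif3j1 and Eif3a fell by 1.13 ± 0.22 and 0.60 ± 0.13 (adjusted p = 0.0463 each). Ckap2l, a spindle protein, and Rest, a repressor of neuronal genes, fell by 0.84 ± 0.17 and 0.67 ± 0.15. The split of 1 higher and 16 lower was 1 and 4 with RLE factors, and 26 and 124 with DESeq2. With RLE factors Eif3j1, Ckap2l and Rest no longer passed (edgeR adjusted p = 0.0535 each), nor did Eif3a (0.0537). The count was 0 without NGC replicate 1, NGC replicate 2 or NG3 replicate 3, 45 without NGC replicate 3, 106 without NG3 replicate 1 and 182 without NG3 replicate 2, and Gm1673 had an adjusted p of 0.0512 without NGC replicate 3. It was also 0 with only NG3 and NGC in the fit. The log2 changes without NG3 replicate 3 were 0.93 for Gm1673, -0.83 for Mphosph8, -0.98 for Eif3j1, -0.40 for Eif3a, -0.59 for Ckap2l and -0.43 for Rest. Eif3j1 had an adjusted p of 0.0564 with the replicate number as a block and of 0.0572 with GC trends removed, in a range from 2.82e-11 to 0.758 over all alternatives.

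Nuclear-retained RNAs were lower in all 6 tested members in NG3 (median -0.50, camera adjusted p = 0.00181, but adjusted p = 0.191 with an estimated correlation). Without NG3 replicate 3 and HGC replicate 2 this list had a camera adjusted p of 0.00174 and was the only list called. Camera also gave lysosome and autophagy (higher, 0.00181), nuclear-encoded respiratory chain (higher, 0.00810), fatty acid synthesis (higher, 0.0395), ribosome biogenesis (lower, 0.0118) and mitochondrially encoded genes (lower, 0.0291). With an estimated correlation the adjusted p of these 5 was 0.395, 0.812, 0.432, 0.432 and 0.608. Adjusted over the list alone, 2 of the 6 nuclear-retained RNAs fell, 1 of 28, 1 of 69 and 1 of 16 members rose in the higher lists, 8 of 24 ribosome biogenesis genes fell and 1 rose, and 3 of 8 mitochondrial genes fell.

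In high glucose edgeR called 0 genes at each dose label with the low-count filter and the 8 groups as the design, and 50 in HG1, 2 in HG2 and 3 in HG3 without the filter. HG1 against HGC (n = 3 each) gave 0 genes in edgeR, 1033 at an unadjusted p under 0.05 and 9 by DESeq2. Its lowest p-values included Ssbp1, a mitochondrial DNA-binding protein (log2 0.99 ± 0.21), Smo, the Hedgehog signal transducer (0.97 ± 0.20), Ndufb3 of respiratory complex I (0.70 ± 0.14), each at adjusted p = 0.136, and Cox17, a copper chaperone of cytochrome c oxidase (0.57 ± 0.13, adjusted p = 0.178). Cytosolic ribosomal proteins had 59 of 68 positive log2 changes in HG1 with a median of 0.15, and 20 rose adjusted over the list alone (camera adjusted p = 3.53e-13, but adjusted p = 0.545 with an estimated correlation). Mitochondrially encoded genes (median 0.28; 2 of 8 rose adjusted over the list alone) and the nuclear-encoded respiratory chain (median 0.05; 6 of 69 rose and 1 fell) were also called by camera, at 0.00275 and 0.0114. Their adjusted p was 0.500 and 0.924 with an estimated correlation. Leaving out HG1 replicate 3 gave 3 genes in place of 0, with Smo at adjusted p = 0.00713 and Ndufb3 at 0.0332. With the replicate number as a block 2 genes passed, Ssbp1 and Ndufb3, at adjusted p = 0.0461 each, and 14 passed with only HG1 and HGC in the fit, among them Ssbp1, Ndufb3 and Cox17. DESeq2 called Smo, Ndufb3 and Cox17 (adjusted p = 0.00434, 0.0151 and 0.0308) and gave no adjusted p for Ssbp1. All 4 genes passed without a low-count filter. Over all alternatives their adjusted p ranged from 4.78e-05 for Ssbp1, 7.29e-07 for Smo, 0.000142 for Ndufb3 and 0.00860 for Cox17 to 0.992 for each.

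HG2 against HGC (n = 2 and 3) gave 0 genes in edgeR, 710 at an unadjusted p under 0.05 and 0 by DESeq2. HG3 against HGC (n = 2 and 3) gave 0, 599 and 0. Adamts1, a secreted metalloproteinase, was among the lowest p-values of both, with log2 changes of -0.68 ± 0.17 (adjusted p = 0.820) and -0.61 ± 0.16 (adjusted p = 0.999) from the same controls. It passed in both without a low-count filter (0.00849 and 0.0409), with a highest adjusted p of 1 over all alternatives. Zkscan17 had -1.005 ± 0.24 in HG2 and Mxd3, a MAX-binding repressor, 0.86 ± 0.23 in HG3. In HG2 cytosolic ribosomal proteins (median -0.13) and the nuclear-encoded respiratory chain (median -0.10) were lower at camera adjusted p = 4.96e-05 and 0.00715, with 0 of 68 and 0 of 69 past adjusted over the list alone. With an estimated correlation the adjusted p was 0.762 and 0.894, and the second was 0.380 by camera without HGC replicate 2 and NG3 replicate 3. No list was called in HG3 (0 by camera and 0 by fry), but camera called 4 without HGC replicate 2 and NG3 replicate 3.

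Txnip, lower in high glucose, had log2 changes of 0.56 ± 0.23, 0.31 ± 0.25 and 0.37 ± 0.25 in HG1, HG2 and HG3 against HGC, and of 0.16 ± 0.22, 0.22 ± 0.22 and 0.37 ± 0.22 in NG1, NG2 and NG3 against NGC. Their edgeR adjusted p was 0.577, 0.964, 0.999, 0.994, 0.949 and 0.576, and the first was 0.0359 without a low-count filter. Irs2 had -0.60 ± 0.23 in HG1 (adjusted p = 0.529), and passed without the filter (0.0244) and with only HG1 and HGC in the fit (0.0396). The highest adjusted p of both genes in HG1 was 0.992 over all alternatives. The median half-width of a gene's unadjusted 95% interval was 0.47 on the log2 scale in NG1 and 0.53 in HG2 and HG3. In simulated counts 1.5-fold changes were called at an adjusted p under 0.05 in 35.8% of genes for NG1 and 14.9% for HG2, and 2-fold changes in 58.2 and 52.2%, so many changes of these sizes were not detectable at this depth and number of libraries.

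Comparisons of doses within a medium asked whether dose labels 3 and 1 differed. mt-Nd5, a mitochondrial complex I gene, had a log2 change of -0.66 ± 0.13 in NG3 against NG1 (adjusted p = 0.0959), and Rplp0, a ribosomal stalk protein, 0.46 ± 0.11 (adjusted p = 0.286). NG3 against NG1 gave 0 genes in edgeR, 871 at an unadjusted p under 0.05 and 1 by DESeq2, but 27 genes without NG3 replicate 2. Without NG1 replicate 1 mt-Nd5 was the 1 gene that passed (adjusted p = 0.00431), and without NG3 replicate 2 it had 0.0142. It also passed in DESeq2 (0.0168), with all 24 files (0.0348) and with the identical file kept in HG2 (0.0478), and both genes passed without a low-count filter (4.65e-06 and 0.0153). The highest adjusted p over all alternatives was 0.911 for mt-Nd5 and 0.998 for Rplp0. In HG3 against HG1 (n = 2 and 3) Ndufa12 of complex I had 0.65 ± 0.13 (adjusted p = 0.212) and Lmnb1, a nuclear lamina protein, 0.62 ± 0.14 (adjusted p = 0.280). That comparison gave 0 genes in edgeR, 877 at an unadjusted p under 0.05 and 1 by DESeq2, which was Ndufa12 (adjusted p = 0.0340). Ndufa12 and Lmnb1 passed without a low-count filter (0.00852 and 0.00531), with only HG1 and HG3 in the fit (0.00978 each) and with all 24 files (0.0492 and 0.0497), and Ndufa12 passed without NG3 replicate 3 and HGC replicate 2 (0.0432). Their highest adjusted p over all alternatives was 0.999. Cytosolic ribosomal proteins were higher in NG3 (camera adjusted p = 0.0327; 2 of 68 rose adjusted over the list alone) and lower in HG3 (3.57e-06; 11 of 68 fell), with adjusted p = 0.881 and 0.694 with an estimated correlation. The call in NG3 had an adjusted p of 0.907 without NG3 replicate 3 and HGC replicate 2. Cholesterol synthesis was lower in HG3 than in HG1 (median -0.23, camera adjusted p = 0.0222, but adjusted p = 0.455 with an estimated correlation; 0 of 25 fell adjusted over the list alone).

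Whether the response to a dose label differed between the media was tested as an interaction. Celf4, an RNA-binding protein of neurons, had positive differences of 0.82 ± 0.18, 0.76 ± 0.19 and 0.93 ± 0.19 on the log2 scale for dose labels 1, 2 and 3, with edgeR adjusted p = 0.131, 0.368 and 0.170. These 3 differences share the HGC and NGC libraries, so they are not independent of each other. For dose label 1, Cyp4v3 had -1.97 ± 0.40 and Cd9 0.93 ± 0.20 (adjusted p = 0.131 each). Lxn had -0.87 ± 0.18 for dose label 2 (adjusted p = 0.368) and Itm2c -0.83 ± 0.18 for dose label 3 (adjusted p = 0.175). With the low-count filter no gene passed in edgeR for dose labels 1, 2 and 3 (0 each; 35, 8 and 30 without it), with 981, 847 and 1091 genes at an unadjusted p under 0.05, and DESeq2 called 11, 0 and 24. Leaving out HG1 replicate 3 gave 3 genes for dose label 1, with Cyp4v3 at adjusted p = 0.0419 and Cd9 at 0.0305. Leaving out NG3 replicate 2 gave 5 for dose label 3, with Celf4 at 0.0222. DESeq2 called Celf4 for dose labels 1 and 3 (adjusted p = 0.0224 and 0.0105), Cd9 (0.0247) and Itm2c (0.0170), and gave no adjusted p for Cyp4v3. All the genes named here passed in edgeR without a low-count filter (0.00121 to 0.0341), apart from Celf4 for dose label 2. Cyp4v3 and Celf4 for dose label 1 (0.0398 each) and Lxn (0.0414) passed with only the compared groups in the fit, and Celf4 and Itm2c for dose label 3 (0.0491 each) with all 24 files. The highest adjusted p of these genes over all alternatives ranged from 0.437 for Cyp4v3 to 0.9996 for Lxn and for Celf4 at dose label 2.

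With 0, 1 and 17 genes called in NG1, NG2 and NG3 and 0 in each of HG1, HG2 and HG3, the overlap of calls cannot show whether dose effects were shared. Tmtc1 in NG2 and Gm1673 in NG3 also rose between HGC and NGC, 1 shared gene each where 0.0189 would be shared by independent lists; these comparisons share the NGC libraries. Across genes, which are not independent replicates, the log2 changes of NG1 and NG2 correlated with r = 0.518, those of NG1 and NG3 with 0.428 and those of NG2 and NG3 with 0.481. Simulated unchanged groups against the same controls gave means of 0.494, 0.485 and 0.497. In high glucose r was 0.393, 0.477 and 0.440 for HG1 with HG2, HG1 with HG3 and HG2 with HG3, with simulated means of 0.435, 0.436 and 0.381. The covariances in normal glucose were 0.0752, 0.0706 and 0.0778, beside simulated 0.0685, 0.0682 and 0.0686. In high glucose they were 0.0819, 0.0975 and 0.0986, beside 0.0744, 0.0740 and 0.0743. Those of NG1 with NG2, NG2 with NG3, HG1 with HG3 and HG2 with HG3 lay above the highest of 20 simulations (0.0719, 0.0775, 0.0764 and 0.0791). The same held in genes of at least 5 CPM and without NG3 replicate 3 and HGC replicate 2, except for HG1 with HG3 in genes of at least 5 CPM (0.0307, highest simulated 0.0312). In those genes the covariance of HG1 with HG2 was 0.0225, below the lowest simulated 0.0274. The correlations of NG1 with NG3 and HG1 with HG2 over all genes lay below their lowest simulated values (0.463 and 0.410), and those of NG1 with NG2, HG1 with HG3 and HG2 with HG3 above their highest (0.517, 0.452 and 0.404). The simulations drew each gene independently, whereas genes can move together between libraries (estimated correlation of cytosolic ribosomal proteins 0.318). Their ranges are therefore likely too narrow, and a value outside them does not by itself mark a dose effect.

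HGC enters the dose effects in high glucose and the glucose effect (HGC against NGC) with opposite signs, so these correlate negatively with no dose effect at all. Observed correlations were -0.459, -0.418 and -0.447 for HG1, HG2 and HG3, and simulated means -0.508, -0.445 and -0.444. That of HG1 was closer to 0 than the whole simulated range (-0.529 to -0.496), and those of HG2 and HG3 lay within theirs (-0.471 to -0.414 and -0.464 to -0.427). The simulated groups held no difference between the media, whereas the real controls differed. That difference alone widens the glucose effect and brings correlations with it closer to 0 in both media, so these ranges cannot judge them. The covariances were -0.0914, -0.0912 and -0.0956, beside simulated means of -0.0739, -0.0744 and -0.0736, and each lay beyond the lowest of 20 simulations (-0.0777, -0.0805 and -0.0776). Without HGC replicate 2 and NG3 replicate 3 the covariance of HG2 was -0.109, within its simulated range of -0.115 to -0.0974. In normal glucose the correlations of NG1, NG2 and NG3 with the glucose effect were 0.410, 0.405 and 0.346, beside simulated 0.477, 0.490 and 0.482 and below the lowest simulated (0.463, 0.472 and 0.463), and the covariances 0.0719, 0.0698 and 0.0675, beside 0.0676, 0.0680 and 0.0680. The controls were not split, since 3 libraries per medium do not leave 2 for each of 2 comparisons, so part of any excess in these covariances or in those between dose labels may come from the shared controls.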

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

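Of the tests in this part, those on whole chromosomes, on a batch that coincides with the medium, on the called NG3 genes alone and on an equal fall of Txnip and Arrdc4 were chosen after the result was seen, as were the fit without NG3 replicate 3 and HGC replicate 2 and the count of media in the drawn splits.

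Camera called a different response to a dose label between the media in 13 list tests. None of them passed with an estimated correlation. All 3 interactions subtract the same difference between HGC and NGC. A list that is high or low in these control libraries by chance can therefore recur at each dose label with the opposite sign and no dose effect. For dose label 1 the difference (HG response minus NG response) was positive for cytosolic ribosomal proteins (median log2 0.28, adjusted p = 1.26e-11), TCA cycle genes (0.16, 0.0175) and mitochondrially encoded genes (0.33, 0.0175). It was negative for lysosome and autophagy genes (-0.15, 0.0175) and for insulin, IGF and leptin signalling (-0.16, 0.0345). With an estimated correlation all 5 had an adjusted p of 0.393. For dose label 2 it was positive for ribosome biogenesis (0.27, 2.88e-05) and negative for fatty acid synthesis (-0.20, 0.0133) and lysosome and autophagy (-0.15, 0.00214), with adjusted p = 0.175, 0.269 and 0.280 with an estimated correlation. For dose label 3 it was positive for mitochondrially encoded genes (0.30, 0.0116) and ribosome biogenesis (0.27, 0.00168). It was negative for cholesterol synthesis (-0.21, 0.0116), fatty acid synthesis (-0.18, 0.0301) and lysosome and autophagy (-0.20, 0.000322). With an estimated correlation the first had an adjusted p of 0.251 and the other 4 of 0.1997. Without NG3 replicate 3 and HGC replicate 2, camera called 6, 3 and 2 lists for the 3 dose labels.

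Reads counted outside genes were above the highest control library in every NG2 library (mean 18.7%, range 18.18 to 19.28%, n = 3; highest NGC 18.15%) and in both HG2 libraries (mean 19.4%, range 18.571 to 20.23%, n = 2; highest HGC 18.563%). Reads aligned to several places were above the highest control in both HG3 libraries (mean 17.6%, range 17.5 to 17.6%, n = 2; highest HGC 17.2%). These are 3 of 18 such comparisons, where chance puts all of 3 libraries above 3 controls in 5% of cases and 2 libraries in 10%, or 1.2 of the 18.

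For the difference between the media, the largest size of a chromosome's median log2 change was 0.0417, over 20 chromosomes with at least 100 tested genes. This argues against a gain or loss of a whole chromosome shared by the libraries of 1 medium. It cannot speak to a change in single libraries, which the mean over the dose levels would dilute. In the real grouping 1340 genes were called over all dose levels. Of 100 drawn splits 1, the real one, gave as many, the highest other giving 86, which argues against a chance allocation of these libraries. The splits cannot speak to a chance difference between cultures, since no label says that replicates came from separate cultures. For HGC against NGC 1 of 10 splits gave the real 303 genes and the highest other gave 1, but 10 splits are too few for a share under 0.05. A culture or library batch that coincides with the medium cannot be told apart from glucose, because no label gives a batch that holds both media. The sign shared at all 4 dose levels by 88.3% of called genes would follow from either, and in part from calling genes on the mean of these levels.

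NG3 replicate 3 stood apart from the other libraries, and NG3 was the only dose group with over 1 called gene. Removing each library's trend on transcript GC content left 17 genes called between NG3 and NGC, 15 of them the same. The genes called before had a median size of 0.57 after removal and 0.61 before. The median of their single-gene standard errors was 0.12 and 0.13. This argues against GC composition as the whole cause. A dose effect shared by the other NG3 libraries is argued against for most of what set this library apart. Genes were picked on it alone against NGC, with the spread taken from the other groups. Their median signed change in NG3 replicates 1 and 2 against the NG1 and NG2 libraries was 0.00657 (interquartile range -0.10 to 0.12). NG3 replicate 3 itself had 0.79, a value that picking the genes on it raises. For the 17 called genes the same median was 0.207, with 17 of 17 in the same direction. All 17 kept their sign against NGC without NG3 replicate 3, with a median size of 0.43, a median single-gene standard error of 0.12 and a lowest edgeR adjusted p of 0.244. As these genes were picked on these libraries, a dose effect and a property of NG3 replicate 3 cannot be told apart for them.

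Txnip, which high glucose induces in many cells, was lower in high glucose here. A single library as the cause is argued against, since the highest adjusted p over 22 fits that left out 1 library was 0.0105 (range from 8.15e-05). A GC trend is argued against too, with a log2 change of -0.62 after its removal (± 0.12, adjusted p = 0.00222). The lower 95% bound of the Arrdc4 change was -0.263, above the Txnip interval of -0.85 to -0.37, which argues against an equal fall of both targets. A response of Txnip itself to the medium, and the batch that coincides with it, stay open as untested hypotheses.

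For the remaining comparisons with 3 libraries per group the 10 splits are too few for a share under 0.05. In NG3 against NGC 1 of 10 splits gave the real 17 genes, and the highest other gave 3. In NG1 against NGC, HG1 against HGC and NG3 against NG1, 10 of 10 splits gave as many genes as the real 0, as any split must, the highest other being 0 in each. In NG2 against NGC it was 2 of 10, with 1 gene in the real split and 1 in the highest other. For the interaction of dose label 1, 100 of 100 drawn splits gave at least the real 0 genes, as any split must, so this count says nothing about chance. The highest other gave 625, which points to a structure of the samples. In that split the media of the controls were exchanged, so that the interaction held 2 times the difference between the media. The 36 splits in which that difference cancelled gave 0 genes each.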

How the results depend on the processing

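The fits that treat the identical file, leave out NG3 replicate 3 and HGC replicate 2, or remove GC trends were chosen after seeing the data. Over alternatives other than leaving out 1 library, named genes kept direction and side of the threshold in 974 comparisons, came to pass in 59, no longer passed in 21 and reversed in 1. Leaving out 1 library gave 1303, 8, 30 and 5. These tallies cover only genes named in this text. Those for HGC against NGC were, apart from Irs2 and the fixed set, picked because they held in every fit that left out 1 library. Their part of the second tally was thus fixed in advance, and of the 20 largest changes there 7 held in all such fits. The glucose counts stayed within 1.5 times of 303 and 1340 under all alternatives but the omission of 1 library, with 279 to 391 and 1284 to 1717. The cause of the changes below was not tested, except that fits of fewer libraries or groups have fewer degrees of freedom. Depth limits the genes tested, and the medium effect is confounded with any batch.

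Counts of called genes changed as follows. DESeq2 gave 25 in NG2, 150 in NG3, 9 in HG1, 1 in NG3 against NG1, 1 in HG3 against HG1, and 11 and 24 for the interactions of dose labels 1 and 3. RLE factors gave 5 in NG3. Without a low-count filter (28284 genes) there were 21 in NG2, 186 in NG3, 50 in HG1, 2 in HG2, 3 in HG3, 14 in NG3 against NG1, 24 in HG3 against HG1, and 35, 8 and 30 for the interactions. Of these only 2 in NG3 lay in genes the filter removes. With only the compared groups in the fit there were 2 in NG2, 0 in NG3, 14 in HG1, 1 in NG3 against NG1, 7 in HG3 against HG1, and 12 and 2 for dose labels 1 and 2. All 24 files gave 53 in NG3, 1 in NG3 against NG1, 6 in HG3 against HG1 and 4 for dose label 3, and the identical file kept in HG2 gave 1 in NG3 against NG1. Without NG3 replicate 3 and HGC replicate 2 there were 17 in NG2, 0 in NG3 and 1 in HG3 against HG1.

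Leaving out 1 library gave 163 to 258 genes for HGC against NGC, 958 to 1597 over all dose levels, 0 to 1 in NG2, 0 to 182 in NG3, 0 to 3 in HG1, 0 to 27 in NG3 against NG1, 0 to 3 and 0 to 5 for the interactions of dose labels 1 and 3, and 0 in the other comparisons. The log2 change of Arrdc4 changed sign, with a range of -0.61 to 0.0648 between HGC and NGC and of -0.0532 to 0.23 over all dose levels, where all 24 files gave -0.0114. That of Txnip ranged from -0.0399 to 0.43 in NG1 and from -0.0849 to 0.49 in NG2. Where omission leaves 1 library in HG2 or HG3, that library is assumed to vary like the other groups.

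Camera with an estimated correlation called 6 lists in HGC against NGC, 8 over all dose levels, 1 in NG2 and 0 in the other comparisons. Fry called 15 lists in HGC against NGC and 18 over all dose levels. It called 2 in NG2, 1 in NG3 and 0 in NG1, HG1, HG2, NG3 against NG1, HG3 against HG1 and the interactions. Between HGC and NGC, fry but not camera called AMPK and mTOR, the integrated stress response, hypoxia, DNA replication, and fibroblast and pericyte markers. Without NG3 replicate 3 and HGC replicate 2 camera called 1 in NG3, 4 in HG3, 0 in NG3 against NG1 and 2 for dose label 3. All 24 files gave 2 in HG3 and 3 in HG3 against HG1.

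With the replicate number as a block HG1 had 2 genes and HG3 had 3 lists, and counts in the other comparisons stayed within 1.5 times. The numbers do not pair the samples: 70 same-number pairs had a median correlation of deviations of 0.0107 (-0.108 to 0.165), 1 above 0.1, and 7 of 22 libraries correlated best with their own number.

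Some covariances of fold changes moved into or out of their simulated range, which is likely too narrow because genes were drawn independently. The simulated groups held no difference between the media, so an r with the glucose effect below the simulated ones is no sign of a dose effect. In genes of at least 5 CPM, NG1 with NG3 moved above it (covariance 0.0337, highest simulated 0.0294, r = 0.515), HG1 with HG2 below it (0.0225, lowest 0.0274, r = 0.303) and HG1 with HG3 into it (0.0307, r = 0.425). NG1, NG2 and NG3 with the glucose effect moved above it (0.0339, 0.0331 and 0.0314, highest 0.0301, 0.0302 and 0.0300), while their r of 0.456, 0.427 and 0.353 lay below the simulated ones. Without NG3 replicate 3 and HGC replicate 2, NG1 with NG3 moved above the range (0.0690, highest 0.0670, r = 0.402) and HG2 with the glucose effect into it (-0.109, r = -0.476). NG1 and NG2 with the glucose effect moved above it (0.0653 and 0.0669, highest 0.0634 and 0.0649), with r of 0.367 and 0.382 below the simulated ones.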

Other observations

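The levels in this part come from lists fixed with the design, and they were looked at after the comparisons. Genes listed as markers of several cell types had counts, but no list had all its members over 1 CPM. Over the 22 libraries the collagen genes Col1a2 and Col1a1 reached 3308 ± 524 and 1364 ± 167 CPM (mean ± SD) and Vim, the intermediate filament gene of mesenchymal and glial cells, 3267 ± 329 CPM. The peptide-processing enzyme gene Cpe stood at 756 ± 54.9 CPM, Ncam1 at 374 ± 49.4, Bdnf at 249 ± 42.4, the neuronal tubulin gene Tubb3 at 58.6 ± 7.05 and Map2 at 47.4 ± 8.80. The neuronal markers Eno2, Stmn2 and Uchl1 stood at 24.6, 17.9 and 14.2 CPM, and 6 of the 20 neuronal markers had a mean over 10 CPM. Neuronal markers near or below detection included Rbfox3 (0.12 CPM), Snap25 (0.035), Syt1 (0.16), Dcx (0.085) and Elavl4 (no count). Of the fibroblast and pericyte markers, 9 of 12 had a mean over 1 CPM, as had 11 of 20 neuronal markers, 7 of 14 astrocyte and tanycyte markers, 4 of 11 oligodendrocyte markers, 4 of 13 microglia markers and 3 of 10 endothelial markers. Of the oligodendrocyte markers over 1 CPM, Cspg4 and Pdgfra are also in the fibroblast list, while Olig1, Olig2 and Sox10 had no count. The astrocyte markers Aqp4 and Gfap stood at 0 and 0.058 CPM, but Nes, Gja1 and Glul of that list at 79.5, 57.2 and 39.3 CPM. The microglia marker Itgam stood at 0, but Tmem119 of that list at 159 CPM.

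Genes of feeding peptides and sweet taste were near or below detection at this depth. Among 33 hypothalamic neuropeptide and receptor genes 5 had a mean over 1 CPM and 11 had no count, and among 23 neurotransmission genes the numbers were 6 and 9. Over 22 libraries Npy had 1 count in all, Agrp 14, Pomc 10, Lepr 10 and Cartpt 0. Of 18 genes of sweet taste and glucose sensing 1 exceeded 1 CPM, Itpr3 at 73.2 ± 9.45 CPM, and 4 had no count. The sweet taste receptor genes Tas1r2 and Tas1r3 had 8 and 26 counts in all and the sodium-glucose transporter gene Slc5a1 0, where a count of 0 allows up to 3 over these libraries.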
